A study of Apis mellifera with 6 samples.

How the data were processed

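Whole-body RNA of 6 overwintering honey bees was compared, 3 labelled healthy and 3 labelled diseased. Per the labels' protocols, RNA was extracted with TRIzol, purified on columns, depleted of ribosomal RNA with a kit made for human, mouse and rat RNA, and made into TruSeq libraries from random hexamers. Per the submitters' processing notes, TopHat 1.4.1, Bowtie2 2.2.3 and Bowtie were used. The classifier and its database, the Cufflinks version and the genome build name are not given in the sources used here.

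The authors deposited 1 list per library of whole-number read counts per taxonomic node, each with its lineage. Reads stop at the lowest node they were assigned to, so the counts are not cumulative, and a clade value here is the sum over its nodes. The lists hold 49195 distinct nodes. They hold no gene counts. The authors also deposited 1 Cufflinks assembly per library with an FPKM, its 95% limits and a coverage for each transcript, per the file attributes. Transcripts were assembled in each library separately and their identifiers cannot be joined across libraries. The coordinates are on RefSeq honey bee sequences of an older build than the available gene table, so no host gene was named.

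Before the data were examined, a gene-level count test, 38 gene lists with set tests, and a rule for named genes were fixed. The count lists turned out to hold taxa and the assemblies hold no gene names, so the gene-level count test, the gene lists and the parts of the rule that need gene names could not be run. Of that rule, the part on features that are not bee genes was kept: each virus, microsporidian, trypanosomatid, mite or bacterial node above 100 reads in any library. Its 54 virus nodes and 1178 bacterial nodes are summarised by counts. For host loci, at most 2 higher and 2 lower were named, those of largest fold change among called loci whose groups did not overlap and whose mean was at least 5 FPKM in the higher group. The limma fit of log2(FPKM + 1) without scaling was among the alternatives fixed beforehand and took the place of the main test. The 68 taxa compared and described, the joining of loci, the filter on mean FPKM, the node test and the median-ratio scaling were chosen after the data were examined. Fits with and without that scaling, for 3 ways of joining transcripts, were run before the unscaled fit of intron-joined loci was kept as the main one.

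Taxa were expressed as reads per 1000000 classified reads (RPM) and compared on log2(RPM + 1) by exact two-sided permutation over all splits of 3 against 3, whose smallest p is 0.1, with Benjamini-Hochberg adjustment over the 68 taxa. Nodes with at least 10 reads in at least 3 libraries were fitted with limma-voom, with the classified reads as library sizes and robust moderation. For loci, introns that occur together in a transcript were linked. The value of an intron was the summed FPKM of the transcripts carrying it, and the value of a locus was the median over its introns assembled in at least 2 libraries. Loci with a mean of at least 1 FPKM were fitted with limma-trend on log2(FPKM + 1), which understates the fold of low loci. Transcripts without introns were left out of the locus test. A locus listed at 0 is one with none of its introns assembled in that library, or with a median of 0 over them, and is not taken as a measure of absent RNA. The mitochondrial genome, which every cell uses, had no transcript listed in any healthy library.

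Depth behind the FPKM values was read from the width of their 95% limits. Single-isoform transcripts of at least 5000 nt imply about 14800000, 22200000 and 18600000 fragments in healthy replicates 1, 2 and 3, and 28500000, 28900000 and 18000000 in diseased replicates 1, 2 and 6, so diseased replicates 1 and 2 were deeper than each healthy library and diseased replicate 6 was not. Transcripts under 150 nt took at least 99.2% of the FPKM sum of each library, so sums of FPKM were not used. The 95% Wilson intervals and the limit of 3 reads for 0 cover counting error only.

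Both fits were tested on simulated data with 200 changed features. Over 7956 loci, 39 of 100 loci changed by 2 (log2) and 75 of 100 changed by 4 were recovered, with 10 false calls. Over 3529 nodes, 81 of 100 and 95 of 100 were recovered, with 8 false calls. Changed loci were drawn from those with a mean log2(FPKM + 1) above 4, and changed nodes from those averaging at least 100 reads. The spread of the most variable nodes was capped in the simulation. Locus noise was simulated as normal and independent, with no loss to 0 by assembly and no shift of a whole library. In the data 23 of the 24 called loci were at 0 in at least 1 library. The shares and false calls therefore do not apply to such loci. They also do not apply to features below those levels or to the most variable nodes. Alternatives covered the pseudocount, the filters, the scaling, the denominator, the joining of loci, the replicate number as a block, and each library left out in turn. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.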

Results

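Total RNA from the whole body of overwintering honey bees (Apis mellifera) was sequenced in 6 libraries, 3 labelled healthy (replicates 1, 2 and 3) and 3 labelled diseased (replicates 1, 2 and 6). The labels give a diagnosis for each bee and name no pathogen. The study's stated design follows a screen of overwintering bees for pathogens, so the comparison asks what differs between bees with and without that diagnosis. Each library came with a list of read counts per taxonomic node and a separate Cufflinks transcript assembly. The classified reads numbered 29434736, 27723901 and 21902309 in healthy replicates 1, 2 and 3, and 19304983, 22444551 and 27834183 in diseased replicates 1, 2 and 6. Nodes ancestral to the honey bee, which other organisms share, held between 78.6% (healthy replicate 1) and 91.6% (diseased replicate 6) of them. Among these nodes, the root of cellular organisms held between 17.0% (healthy replicate 1) and 31.5% (diseased replicate 6). The insect clade held between 20.3% (healthy replicate 1) and 32.0% (diseased replicate 1) of the classified reads. Nothing in the labels says that the bees came from separate colonies, so p-values measure the spread between these samples. Intervals below are 95% Wilson intervals and cover counting error only.

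Reads of Israeli acute paralysis virus, a dicistrovirus of honey bees, were more abundant in each of the 3 diseased libraries than in any healthy library. Scaled to 1000000 classified reads (RPM), they were at 13.4 RPM in diseased replicate 1 (interval 11.9 to 15.1), 569 in diseased replicate 2 (559 to 579) and 1488 in diseased replicate 6 (1474 to 1503). The healthy libraries held 1, 0 and 1 such reads, and the limit for 0 reads in healthy replicate 2 is 0.108 RPM. Black queen cell virus, another dicistrovirus, was at 30.4, 43.1 and 1052 RPM in diseased replicates 1, 2 and 6. It was at 10.4 in healthy replicate 1 and 0.0361 in healthy replicate 2, with 0 reads in healthy replicate 3. The whole family Dicistroviridae averaged 1564 ± 1848 RPM in diseased bees (SD, n = 3) and 7.02 ± 10.7 in healthy bees (SD, n = 3). For all 3 of these taxa the groups did not overlap, which gives an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow (Benjamini-Hochberg adjusted p = 0.358 over 68 taxa).

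The highest virus level of the series was in a library labelled healthy. Lake Sinai virus 1 took 1414240 reads in healthy replicate 3, or 6.46% of its classified reads (interval 6.45% to 6.47%). The same virus had 118 reads in healthy replicate 1, 4 in healthy replicate 2, 17 in diseased replicate 6, and 0 in diseased replicates 1 and 2. Lake Sinai virus 2 was higher in each healthy library than in any diseased library. It had 110, 4 and 5110 reads in healthy replicates 1, 2 and 3, and 0, 0 and 2 in diseased replicates 1, 2 and 6. Its exact two-sided permutation p was 0.1 (adjusted p = 0.358), but the intervals of healthy replicate 2 and diseased replicate 6 overlap. Chronic bee paralysis virus was at 42.6 RPM in healthy replicate 3 (934 reads) and had at most 2 reads in each of the other libraries. The family Iflaviridae, which includes deformed wing virus and sacbrood virus, was at 5575 RPM in diseased replicate 6. It was at 98.8, 0.433 and 0.183 in healthy replicates 1, 2 and 3, and at 9.22 and 9.36 in diseased replicates 1 and 2. The family overlapped between the groups (exact two-sided permutation p = 0.5, adjusted p = 0.654). Most of these reads in diseased replicate 6 stopped above the species, at 3847 RPM on the genus node Iflavirus and 1708 on the node of unclassified Iflavirus. The node of deformed wing virus itself was at 12.5 RPM there (348 reads) and had at most 3 reads in each other library, and any reads of that virus on higher nodes are not counted in it. Total virus reads did not separate the groups (exact two-sided permutation p = 0.8, adjusted p = 0.892). They include reads placed on human immunodeficiency virus 1, at 674 of 1359 RPM in healthy replicate 1 and 440 of 967 in healthy replicate 2. In each other library these were at 27.4 to 35.0 RPM. Whether they were misplaced was not tested, so total virus reads are not a measure of bee virus load. Without healthy replicate 3 the log2 difference of total virus reads changed from -0.80 to 1.21, diseased minus healthy, and without diseased replicate 1 it was 0.09.

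Plant viruses also differed between individual libraries. Tomato ringspot virus had 13856 reads in diseased replicate 2, 58 in diseased replicate 1 and 35 in diseased replicate 6, against 2 in each healthy library (exact two-sided permutation p = 0.1, adjusted p = 0.358). Tobacco streak virus had 10121 reads in healthy replicate 3 and between 4 and 20 in the other 5 libraries.

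**Figure D1:**
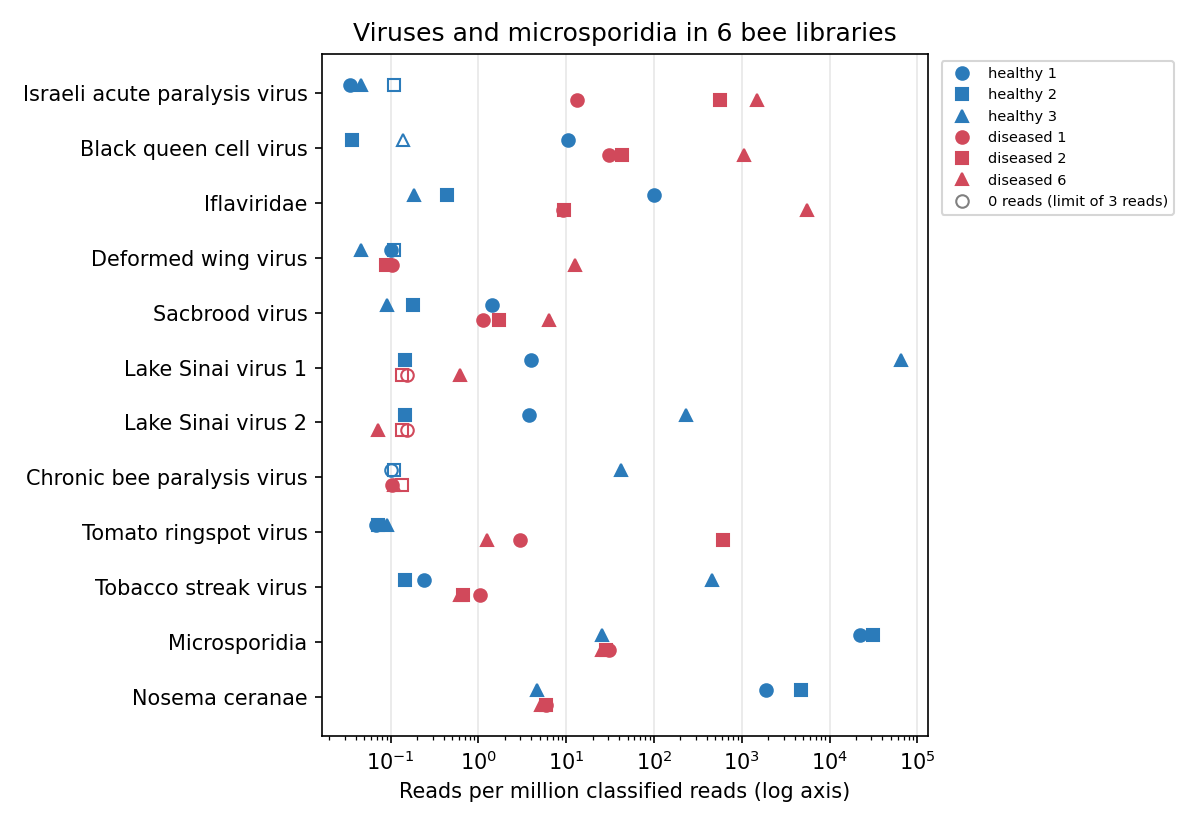
Reads per 1000000 classified reads (RPM, log axis) of viruses and microsporidia in the 3 healthy (blue) and 3 diseased (red) libraries, 1 point per library. Open points mark 0 reads and stand at the limit of 3 reads. Israeli acute paralysis virus lies at 13.4 or more in the diseased libraries, and microsporidia lie at 22364 and 31240 in healthy replicates 1 and 2.

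Microsporidia, the parasite group that holds Nosema, were abundant in 2 libraries labelled healthy and far lower in the remaining 4. They made up 2.24% of classified reads in healthy replicate 1 (interval 2.23% to 2.24%) and 3.12% in healthy replicate 2 (3.12% to 3.13%). In healthy replicate 3 they were at 25.4 RPM, and in the diseased libraries at 31.0, 28.7 and 25.8. Nosema ceranae, the species with the most reads of its genus, was at 1883 and 4748 RPM in healthy replicates 1 and 2, against 4.66 to 5.96 in the other 4 libraries. The group comparison of microsporidia gave an exact two-sided permutation p of 0.4 (adjusted p = 0.579). Reads placed on trypanosomatids were at 352 ± 98.2 RPM in healthy bees and 503 ± 96.5 in diseased bees (SD, n = 3 each; exact two-sided permutation p = 0.2, adjusted p = 0.439). They lay on Leishmania and Trypanosoma nodes in all 6 libraries, while Crithidia, a genus with gut parasites of bees, had 11 to 26 reads per library. Of 12 trypanosomatid and 12 microsporidian nodes above 100 reads, 3 of each were higher in each diseased library than in any healthy one and 0 lower. That is 25.0% of each, against 38.0% of the 721 other nodes described below. Per read of the insect clade, 5 trypanosomatid and 1 microsporidian nodes were higher and 0 lower. Reads placed on Varroa, the parasitic mite genus, numbered 1, 6 and 5 in the healthy libraries and 15, 15 and 9 in the diseased ones (exact two-sided permutation p = 0.1, adjusted p = 0.358). Mites as a whole (Acari) averaged 108 RPM in healthy bees (range 87.5 to 145, n = 3) and 112 in diseased bees (range 98.0 to 120, n = 3; exact two-sided permutation p = 0.8, adjusted p = 0.892), and of 4 mite nodes above 100 reads 0 were higher and 2 lower in each diseased library than in any healthy one. The classifier and its database are not given in the sources used here, and background from misplaced reads was not measured for trypanosomatids or Varroa.

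Among bacteria, Bifidobacterium, a genus of the bee gut, was higher in each healthy library than in any diseased library. It averaged 224 ± 81.2 RPM in healthy bees (SD, n = 3) and 74.4 ± 30.5 in diseased bees (SD, n = 3), a ratio of 3.01. Within it, Bifidobacterium asteroides was at 195, 248 and 106 RPM in healthy replicates 1, 2 and 3, and at 3.21, 63.1 and 35.6 in diseased replicates 1, 2 and 6. Paenibacillus larvae, known as the agent of American foulbrood in larvae, was at 6.90, 13.3 and 9.63 RPM in healthy replicates 1, 2 and 3, and at 15.3, 50.6 and 114 in diseased replicates 1, 2 and 6. Each of these comparisons had no overlap between groups, with an exact two-sided permutation p of 0.1 (adjusted p = 0.358). Per read of the insect clade Paenibacillus larvae overlapped between the groups (exact two-sided permutation p = 0.2). Lactobacillus overlapped, at 324 ± 113 against 179 ± 52.8 RPM (SD, n = 3 each; exact two-sided permutation p = 0.2, adjusted p = 0.439), but not per read of the insect clade (exact two-sided permutation p = 0.1). Bartonella was at 148 and 114 RPM on average, and was highest in healthy replicate 3, at 279 (exact two-sided permutation p = 0.9, adjusted p = 0.987). Neisseriaceae and Acetobacteraceae were each highest in diseased replicate 6, at 112 and 108 RPM. Total bacterial reads were at 48436, 16694 and 17496 RPM in healthy replicates 1, 2 and 3, above the 16104, 14452 and 14989 RPM of diseased replicates 1, 2 and 6 (exact two-sided permutation p = 0.1, adjusted p = 0.358). Of the 1425698 bacterial reads in healthy replicate 1, 1102259 lay on 6 nodes chosen after the values were seen, each above 50000 reads there and at least 10 times its RPM in any diseased library. With healthy replicate 1 left out the log2 difference of total bacteria, diseased minus healthy, went from -0.67 to -0.17.

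**Figure D2:**
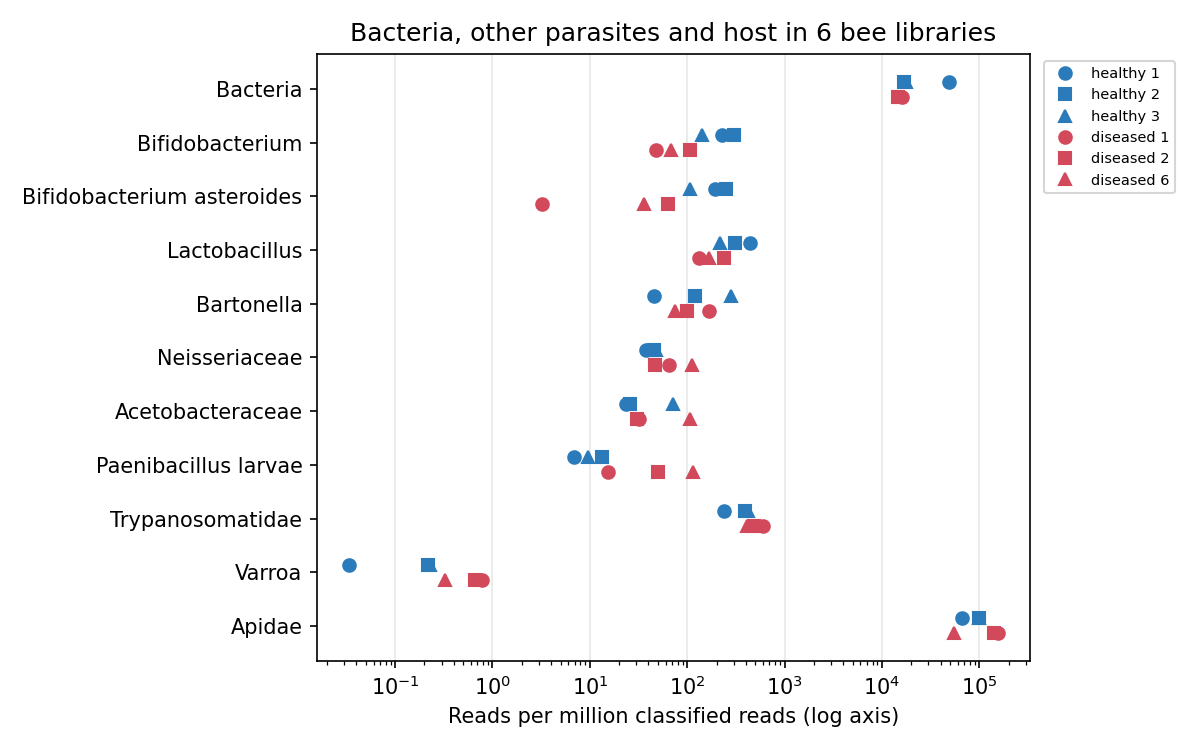
Reads per 1000000 classified reads (RPM, log axis) of bacteria, other parasites and the bee family in the 3 healthy (blue) and 3 diseased (red) libraries, 1 point per library. Bifidobacterium lies between 141 and 303 in the healthy libraries and between 47.8 and 108 in the diseased ones.

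Of 54 virus nodes above 100 reads in any library, 12 were higher in each diseased library than in any healthy one and 3 were lower. Of 1178 bacterial nodes above the same minimum, 473 were higher in each diseased library and 26 were lower. Of the 721 nodes outside the viruses, bacteria, microsporidia, trypanosomatids and mites, host lineage included, 274 were higher and 19 lower, so 38.0% were higher against 40.2% of the bacterial nodes. Chance gives 10% of nodes without overlap in either direction for 3 libraries against 3. In either direction the shares were 42.4% for bacterial nodes, 40.6% for the 721 other nodes and 27.8% for virus nodes. Counted per read of the insect clade, which was a larger share of diseased replicates 1 and 2 than of the healthy libraries, these numbers were 262 and 30 for bacteria, 193 and 28 for the 721 other nodes, and 9 and 3 for viruses. A limma-voom fit of 3692 nodes called 0 nodes higher and 0 lower in diseased bees at an adjusted p under 0.05, with 617 and 39 at an unadjusted p under 0.05. With median-ratio scaling these last numbers were 145 and 175, and per read of the insect clade 328 and 70, with 0 nodes called under both. Limma-trend on log2(RPM + 1) called 2 and 0. The fitted log2 fold change of Israeli acute paralysis virus was 12.38 ± 3.92 (SE; limma-voom adjusted p = 0.266). With 1, 0 and 1 reads in the healthy libraries its size depends on the offset: the log2 difference was 7.81 on log2(RPM + 1), 10.82 with a pseudocount of 0.1 and 4.77 with 10. Counts higher and lower were 0 and 2 without healthy replicate 1, 2 and 0 without healthy replicate 2, and 3 and 13 without healthy replicate 3. They were 25 and 18 without diseased replicate 1, 0 and 1 without diseased replicate 2, and 106 and 23 without diseased replicate 6.

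The transcript assemblies were joined into 9417 loci by shared introns. They name no gene, so host loci are given by position. A limma-trend fit of log2(FPKM + 1) over 7956 loci called 17 higher and 7 lower in diseased bees at an adjusted p under 0.05, and in all 24 the groups did not overlap. Of the 17, 14 were listed at 0 FPKM in every healthy library, and of the 7, 4 were listed at 0 in every diseased library. A group listed at 0 throughout adds no spread to the fit, though 0 is not taken as a measure of absent RNA. The SE and p-values of these loci therefore do not measure the spread between bees in that group. The locus with the largest increase lay on the minus strand of linkage group 11, from 4681542 to 4682880. It was at 218, 196 and 57.5 FPKM in diseased replicates 1, 2 and 6 and listed at 0 in the healthy libraries (log2 fold change 7.09 ± 0.53 SE on the log2(FPKM + 1) scale, limma adjusted p = 0.00651). In the healthy libraries transcripts on either strand covered on average 79.1% of its exon bases. Partial transcripts of the locus itself were not set apart in such shares. The next lay on the minus strand of linkage group 12, from 2741482 to 2824620. It was at 43.7, 31.4 and 15.9 FPKM in diseased replicates 1, 2 and 6 and listed at 0 in the healthy libraries (4.86 ± 0.44 SE, limma adjusted p = 0.0124). Transcripts there, possibly partial ones of this locus, covered 44.5% of its exon bases. The largest decrease lay on the minus strand of linkage group 11, from 11774125 to 11778396, at 269, 324 and 1258 FPKM in the healthy libraries. It was at 7.16 FPKM in diseased replicate 2 and listed at 0 in diseased replicates 1 and 6 (-7.90 ± 0.96 SE, limma adjusted p = 0.0335). A locus on a scaffold outside the linkage groups was at 112, 146 and 101 FPKM in the healthy libraries and listed at 0 in the diseased ones (-6.90 ± 0.30 SE, limma adjusted p = 3.6e-04), where other transcripts covered 0% of its exon bases and 3242 fragments would be expected at its healthy level. Under 11 other settings each, these calls held in 9 for the first locus and 5 for that on linkage group 12. They held in 4 for the largest decrease (highest adjusted p = 0.179) and 11 for the scaffold locus. The counts include the replicate block, under which each call held but which estimates the difference from replicates 1 and 2 only.

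The number of called loci depended on the pseudocount and on each library. With a pseudocount of 0.1 FPKM, 1 locus was higher and 1 lower. After scaling by median ratios the split was 14 higher and 11 lower, or 56.0% higher in place of 70.8%. The median shift from the mean of the libraries (log2) was -0.73, 0.07 and -0.05 in healthy replicates 1, 2 and 3, and 0.31, 0.27 and 0.26 in diseased replicates 1, 2 and 6. Counts higher and lower were 3 and 3, 0 and 1, and 4 and 2 without healthy replicates 1, 2 and 3 in turn. They were 3 and 2, 1 and 4, and 25 and 12 without diseased replicates 1, 2 and 6 in turn.

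**Figure D3:**
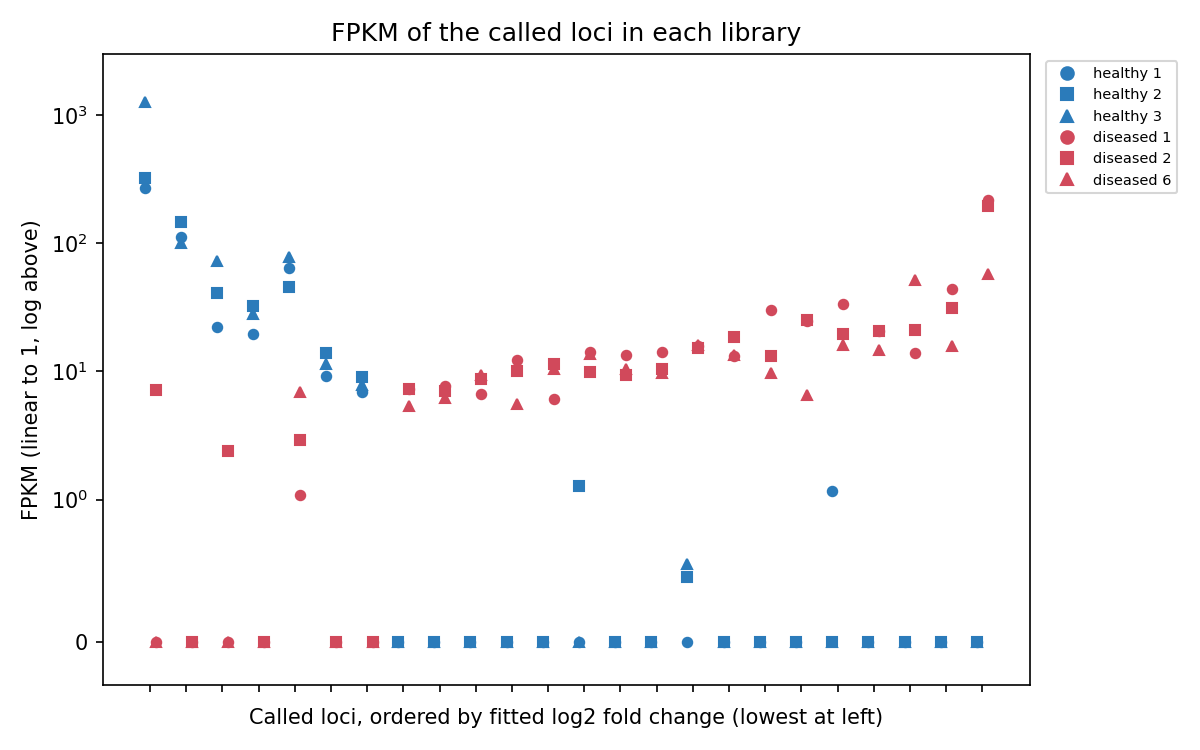
FPKM of the 24 called loci in each library (linear to 1 and log above), with healthy libraries in blue and diseased libraries in red, ordered by fitted log2 fold change. The 7 loci at the left were lower in diseased bees, and the 17 at the right were higher.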

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

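The tests on mitochondrial transcripts and on pathogen reads in this part were chosen after the result was seen, as was that on the 8 uncovered loci; the other tests on loci listed at 0 were written before.

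Mitochondrial transcripts, which no comparison above uses, were listed in the diseased libraries and in no healthy library. Diseased replicates 1 and 2 had 2 short ones each, of 289 to 408 nt, with a highest level of 16.3 and 5.64 FPKM; diseased replicate 6 had 1 of 15533 nt at 2168 FPKM, which stands for 823018 fragments by its 95% limits. For the long transcript, in 1 of 3 diseased libraries, lower depth is argued against, since these would scale to 676771 in the shallowest healthy library; for the short ones depth stays open, with a median of 20.3 expected there. A ceiling on fragments per assembled locus may have removed the long transcript elsewhere: outside the mitochondrion the highest transcript of any library had 616828 fragments by its limits, fewer than the 823018 of the mitochondrial one but not than the 604410 from its FPKM, length and depth, and the assembly settings are not given in the sources used here. As diseased replicates 1 and 2 lacked it too, the long transcript did not follow the diagnosis.

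Of the 24 loci called between groups, 18 were listed at 0 in every library of a group. A median of 224 fragments (39.5 to 3242 per locus) would be expected in the libraries listed at 0, which argues against lower depth for these loci as a set. The expected numbers count fragments over the full transcript length and not those that span an intron. For the loci with the fewest expected fragments, depth therefore stays open in the libraries listed at 0. If the assembler had built the same RNA into other transcripts there, these would cover the loci. The median covered share of exon bases was 15.3%, over 50% at 4 loci and 0 at 8. That share counted transcripts on either strand and did not set apart partial transcripts of the locus itself. At the 8 uncovered loci a median of 100.4 fragments would be expected (39.5 to 3242). These loci were picked because no other transcript covered them, so this test cannot weigh whether the RNA was assembled otherwise. The overall share lies between the bounds set beforehand. Over the 18 loci a difference in assembly may therefore contribute and cannot be told apart from a difference linked to the diagnosis. RNA left out of every transcript was not tested.

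Libraries labelled healthy held the most microsporidian reads (healthy replicates 1 and 2) and the most Lake Sinai virus reads (healthy replicate 3), while each diseased library was above every healthy one in RPM of Israeli acute paralysis virus (means 690 against 0.0265), black queen cell virus (375 against 3.47), Paenibacillus larvae (lowest 15.3 against highest 13.3) and Varroa. Israeli acute paralysis virus, black queen cell virus, Paenibacillus larvae and Varroa run in the direction of the labels. So did 22.2% of virus nodes, 40.2% of bacterial nodes and 38.0% of the 721 other nodes above 100 reads. Lake Sinai virus 2 runs against it, higher in each healthy library (means 79.1 RPM in healthy and 0.0240 in diseased bees). Its healthy mean rests mostly on healthy replicate 3, at 233 RPM. The separation rests on 4 reads in healthy replicate 2 (interval 0.0561 to 0.371 RPM) against 2 in diseased replicate 6 (0.0197 to 0.262). These intervals overlap. The labels name no pathogen, so a swap of labels between the groups stays open. Over loci each healthy library correlated better with both other healthy libraries than with any diseased one, by at least 0.030 in r. An exchange of whole groups would leave this as it is. Diseased replicate 6 correlated less with the other diseased libraries (0.643 and 0.682) than with healthy replicates 2 and 3 (0.702 and 0.708). Bee reads assigned to microsporidian nodes by error would appear in each library, but the phylum node held at most 2 reads in the other 4. Carry-over from 1 library would keep 1 ratio between healthy replicates 1 and 2, but the ratio differed 3.32-fold between microsporidian nodes. Infection of bees that carried a healthy diagnosis, and contamination during preparation, stay open and were not tested.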

How the results depend on the processing

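The bounds for the splits of the samples were written after their counts were seen, and the settings for taxa and nodes, and for loci the scaling, the way of joining and the set of loci, were chosen after the data were examined. The planned gene-level count tests with other scalings and filters, and all gene set tests, were not run because the files name no genes. Loci higher and lower in diseased bees numbered 17 and 7. They numbered 1 and 1 with a pseudocount of 0.1, 0 and 2 among loci present in all 6 libraries (a filter that by itself drops 23 of the 24 called loci), 7 and 6 without healthy replicate 1 and diseased replicate 6 together, 35 and 14 for single introns, 47 and 50 for single introns after median-ratio scaling, 14 and 11 after median-ratio scaling, 10 and 7 for loci joined by overlapping exons with that scaling, 13 and 6 without it, and 16 and 7 with no filter. Leaving out 1 library gave 0 to 25 higher and 1 to 12 lower. Of the 24 called loci, 21 were shared with the scaled fit and 2 with the pseudocount of 0.1. With the replicate number as a block, 492 loci were higher and 68 lower, from 2 shared numbers. The deviations of same-numbered libraries had correlations of -0.115 and -0.053, too few to show whether bees were paired. The labels state no pairing. Nodes higher and lower numbered 0 and 0, against 289 and 103 with no filter on low reads, 2 and 0 with limma-trend, 28 and 42 with the replicate block, 0 and 0 with median-ratio scaling or per insect read, and 0 to 106 and 0 to 23 with 1 library left out. Taxa without overlap numbered 13 with diseased libraries higher and 6 with healthy libraries higher, against 11 and 9 per insect read. With 1 library left out they numbered 15 to 21 and 6 to 15. Leaving a library out cannot make separate groups overlap, so these last counts could not fall and do not test the separation. Of 234 alternatives for 26 taxa, 227 kept the direction. For taxa without overlap, no pseudocount or left-out library could turn the sign, so that part of the 227 was fixed in advance. With 1 library left out the log2 difference ranged from -2.68 to 0.047 for chronic bee paralysis virus and from -3.76 to 0.57 for tobacco streak virus. It ranged from -1.93 to 1.21 for all viruses, from -0.76 to 0.53 for Bartonella and from -0.18 to 0.91 for Acetobacteraceae. For all bacteria it ranged from -0.94 to -0.17. The sign turned without healthy replicate 3 (the viruses and Bartonella), without diseased replicate 1 (all viruses, 0.09) and without diseased replicate 6 (Bartonella, 0.16, and Acetobacteraceae). The cause was not tested. Of 11 alternatives each, the named loci on linkage group 11 passed in 9 (the higher one) and 4 (the lower one), that on linkage group 12 in 5 and that on the scaffold in 11. Each of these counts includes the replicate block.

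Of the 10 splits of the 6 libraries into 3 and 3, the real one called 24 loci and the highest other called 5, with 1 split at the real count or above. For nodes the real split called 0 and the highest other called 2, with all 10 at the real count or above. These splits are too few for a share under 0.05.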

Other observations

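Healthy replicate 1 held a set of 12 nodes outside the microsporidia, each above 50000 reads and at least 10 times its level in any diseased library, that made up 10.7% of its classified reads. The same nodes made up 0.820% in healthy replicate 2, 0.344% in healthy replicate 3, and 0.111%, 0.101% and 0.121% in diseased replicates 1, 2 and 6. They include the node of the strain Agrobacterium sp. H13-3, with 305092, 16214 and 4934 reads in healthy replicates 1, 2 and 3 and 70, 51 and 86 in the diseased libraries. They also include an uncultured Flavobacteriales bacterium, with 116931, 9962 and 2796 reads in the healthy libraries and 0, 0 and 3 in the diseased ones. Mammalian nodes such as Bos (317971, 25217 and 6409 reads against 272, 244 and 163) fell in the same order over the healthy libraries and were lower in each diseased one. These nodes were selected on healthy replicate 1 after their values were seen.

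The node of the strain Rhodococcus sp. DK17 had 4660, 2938 and 3726 reads in the healthy libraries and 775, 896 and 978 in the diseased ones (limma-voom adjusted p = 0.111). A granulovirus of the moth Clostera anachoreta had 6885, 3124 and 3914 against 1177, 651 and 1039 reads (limma-voom adjusted p = 0.171). Alfalfa mosaic virus had 198 reads in diseased replicate 1, 1 in diseased replicate 2, 8 in diseased replicate 6 and 0 in each healthy library. Reads placed on the order Oceanospirillales were at 52.3 ± 16.0 RPM in healthy bees and 162 ± 120 in diseased bees (SD, n = 3 each), with 8344 of them in diseased replicate 6 (exact two-sided permutation p = 0.1, adjusted p = 0.358).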
